A study of Homo sapiens with 4 samples.

How the data were processed

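Total RNA from 4 cultures of stably transfected Raji cells was labelled with biotin and measured on one-colour Affymetrix arrays, 1 array per culture. The labels' protocols give 6 µg of total RNA per array. The authors deposited 1 intensity per probe set and array as a MAS5 signal on a linear scale, and MAS5 is named in the submitters' processing notes without a version. MAS5 combines the probe pairs of a probe set into 1 background-corrected signal and scales each array to a target. The deposited intensities bear out the scaling: the 2% trimmed mean was 250.03 to 250.04 in the 4 arrays, with median signals of 85.6 and 69.2 (titled CD9) and 82.8 and 69.1 (titled mock). Because the scaling equalises array means, a change shared by most transcripts would not be seen. Detection calls and scanner files were not used here, so no probe set could be called absent. All 4 columns of the deposited table were used. For arrays, the number of arrays limits the precision.

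Groups were taken from the titles. The source names give the opposite construct for each array but the same 2 pairs, so the membership of the groups does not depend on the choice and the sign of every difference does. The design, the tests, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except where stated. The CD9 transcript was used only to check the labels, and no array was moved by it.

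Signals were transformed as log2(signal + 21.2), the offset being the 25th percentile of all signals, which understates the change of weakly expressed genes. Control probe sets (62) were left out. Of 54613 others, the 27307 with a mean log2 value over all 4 arrays at or above the median of 6.51 were tested. The groups were compared in limma 3.58.1 (R 4.3.3) with lmFit and eBayes with an intensity trend, without other covariates, and p-values were adjusted by the Benjamini-Hochberg method. A probe set was called at an adjusted p under 0.05. The spread rested on 2 residual degrees of freedom and 4.29 prior degrees of freedom. The test was tried on simulated data with the same means and with variances drawn from the fitted prior. Noise was independent between probe sets and equal across arrays, unlike in the measured arrays, so the rates need not carry over to them. Sizes of change were enlarged after smaller ones were almost never recovered. The test recovered the simulated log2 changes with a median ratio of 1.00, and a mean of 0.05 probe sets was called when none was changed.

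Probe sets were named from GEO's platform annotation. Of those without controls, 41091 had 1 gene symbol, 1801 had several and 11721 had none, and symbols were checked against current RefSeq names through the gene identifiers, which changed none. Probe sets with several symbols were tested but not named, and unnamed probe sets are not without a gene. Probe set suffixes _s_at and _x_at mark probes that can match related transcripts or other sequences. The table holds no genomic positions and names no build, so none are given. The genes named are CD9 and, in each direction, the 12 largest changes past the threshold that separate the groups. Where fewer than 5 passed, the selection was filled up to 5 genes, any that passed included, by smallest unadjusted p. The added ones came from probe sets that separate the groups and differ by at least 1 on the log2 scale. They are said not to pass. From each list up to 4 members with the smallest p were eligible.

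For gene lists each gene was represented by its probe set with the highest mean over the 4 arrays. Lists were tested two-sided with camera at a preset inter-gene correlation of 0.01, with an estimated correlation beside it, and with fry, which tests whether the members move one way on balance without comparing them with other genes. Adjustment was over the 27 lists. In simulated data a list shifted by 0.5 on the log2 scale was found in 100% of 20 runs when genes were independent. Some list members had no probe set naming them alone and are not analysed here.

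The alternatives were other offsets, quantile normalization, rescaling to 1 trimmed mean, other filters, eBayes without a trend, the replicate number as a block, each array left out, genes averaged over probe sets, and estimated list correlation. Array weights were added after seeing the data.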

Results

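Gene expression was measured in Raji, an Epstein-Barr virus-positive human B cell line derived from a Burkitt lymphoma, after stable transfection with a plasmid encoding CD9 or with the empty plasmid. CD9 is a tetraspanin, a small membrane protein with several membrane-spanning segments that associates with integrins and other surface proteins. The design compares the transcript levels of both kinds of transfectant during exponential growth under G418 selection at 1 mg/ml. There were 4 one-colour arrays, 2 titled CD9-transfected and 2 titled mock-transfected, each with 54675 probe sets. The labels call the replicates biological but do not say whether they came from separate transfections or clones, so the tests measure the spread between these arrays. The GEO titles and source names contradict each other: each array titled CD9 has a source name describing the empty vector, and each array titled mock has one describing the CD9 vector. Both fields place the same arrays together. Groups below are therefore "the arrays titled CD9" and "the arrays titled mock", and every difference is the former minus the latter.

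CD9 was the first transcript examined, because it checks the labels. The CD9 probe set with the highest signal gave a MAS5 signal of 14820 and 14022 in the arrays titled CD9 (replicates 1 and 2), against 21.2 and 12.1 in the arrays titled mock. The group means were 14421 ± 564 (SD, n = 2) and 16.6 ± 6.42 (SD, n = 2). The CD9 signal lay at the 99.6th percentile of all probe sets in each array titled CD9, and at the 23.7th and 15.7th percentiles in the arrays titled mock. On the log2(signal + 21.2) scale the difference was 8.59 ± 0.47 (SE), with a 95% confidence interval from 7.44 to 9.73, which is 384-fold on that scale. This passed the limma test (adjusted p = 0.031). The lower of the CD9 signals was 663 times the higher of the mock signals. No detection call accompanies the values, so the mock signals, which lie near the low end of each array, have no known background level. The titles thus matched the CD9 transcript in all 4 arrays and the source names in none. A second CD9 probe set gave 184 ± 30.4 and 163 ± 44.2 (SD, n = 2 each), a log2 difference of 0.17 ± 0.44 (SE, limma adjusted p = 1.00). The third lay below the intensity filter, with signals between 7.96 and 43.2. Which part of the CD9 transcript each probe set measures is not given in the sources used here.

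**Figure D1:**
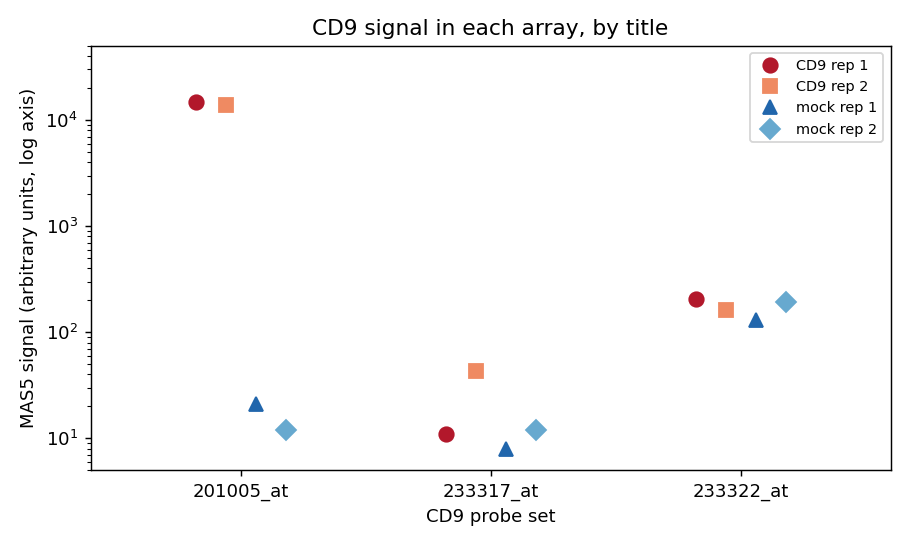
MAS5 signal (vertical log axis, arbitrary units) of the 3 CD9 probe sets in each of the 4 arrays, grouped by title; every point is 1 array. For the first the arrays titled CD9 sit at 14820 and 14022 and those titled mock at 21.2 and 12.1, while the other CD9 probe sets overlap between the groups.

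Across the 27307 probe sets above the intensity filter, CD9 was the only one past an adjusted p of 0.05 in limma, and its change exceeded 2-fold. None passed in the lower direction. At an unadjusted p under 0.05 there were 157 probe sets, 59 higher and 98 lower in the arrays titled CD9, where chance alone would give 1365. The SD of log2 differences was 1.23 between the arrays titled mock and 0.56 between those titled CD9. A wide spread within a group lowers such counts, so a count under chance does not show that the groups are alike. Apart from CD9, the smallest adjusted p was 1.00. A log2 difference of at least 1 was seen at 1408 probe sets, and at 296 (higher) and 291 (lower) of these both arrays of one group lay beyond both of the other. Over all tested probe sets the groups separated in this way at 18.9%, where chance gives 33.3%. In data simulated with the estimated spread, 200 changed probe sets among 27307 were recovered at rates of 0.672% for log2 changes of 2 (4-fold), 48.3% for 4 (16-fold) and 97.0% for 8. The sizes were mixed in each run, which affects the rates. The simulated noise was equal in all arrays, while 1 measured array stood apart, so these rates need not hold here. Under that noise changes of 4-fold or less were mostly not recovered, so failing the test does not make such changes absent.

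One array stood apart from the rest. The SD of log2 differences was 0.56 between the arrays titled CD9, 0.55 between CD9 replicate 1 and mock replicate 1, and 0.63 between CD9 replicate 2 and mock replicate 1. Mock replicate 2 differed from CD9 replicate 1 with an SD of 1.08, from CD9 replicate 2 with 0.95 and from mock replicate 1 with 1.23. Between the arrays titled mock, 10401 of 27307 probe sets differed by at least 2-fold, against 2025 between the arrays titled CD9. The number of probe sets past the threshold was 12 without mock replicate 2 and 5765 without mock replicate 1, when mock replicate 2 alone stood for its group. Of the 111 probe sets other than CD9 that the rule for named genes selects, 35 had the opposite sign without mock replicate 2, and 55 passed without mock replicate 1. In both fits a lone array was assumed to vary like the other group. With either array titled CD9 left out the count was 1, CD9. Of the gene lists, 8 passed without mock replicate 1. Oxidative phosphorylation (median -0.67), MHC class I (-0.84) and class II (-0.73), glycolysis and hypoxia (-0.58), G1/S (-0.50), unfolded protein response (-0.47) and plasma cell genes (-0.45) were then lower in the arrays titled CD9 than in mock replicate 2, and G2/M genes (0.48) higher.

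The probe sets given beside CD9 had the smallest unadjusted p in each direction among those chosen for separating the groups. They did not pass the test, and their values are given as measured (adjusted p = 1.00 in limma for each). Those with higher signals in the arrays titled CD9 were led by PLXNA1, a semaphorin receptor, at 251 and 420 against 28.8 and 15.0. Its log2 difference was 3.03 ± 0.50 (SE), but a second PLXNA1 probe set differed by only 0.16 ± 0.52. ABHD10, a mitochondrial hydrolase, gave 277 and 259 against 35.7 and 34.8, a log2 difference of 2.36 ± 0.43, with 0.46 ± 0.43 at its other probe set. ANK2, an ankyrin that links membrane proteins to the cytoskeleton, gave 888 and 703 against 164 and 133, a log2 difference of 2.26 ± 0.45. Its second probe set differed by 1.67 ± 0.45 in the same direction. ADAM33, a membrane-anchored metalloprotease, differed by 2.06 ± 0.44 at a probe set whose suffix, _x_at, marks probes that can match other sequences.

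Among probe sets with lower signals in the arrays titled CD9, ESD, which encodes S-formylglutathione hydrolase, gave 167 and 206 against 962 and 1466, a log2 difference of -2.55 ± 0.49 (SE). A second ESD probe set differed by -1.86 ± 0.50, and its other 2 by -0.63 ± 0.47 and -0.22 ± 0.70. The remaining 4 had signals of at most 246. CCNP differed by -2.39 ± 0.52, from 12.3 and 28.6 in the arrays titled CD9 to 227 and 164 in those titled mock. PADI2, a peptidylarginine deiminase, differed by -2.12 ± 0.48, PRX, a myelin protein of peripheral nerve, by -2.05 ± 0.46, and NUTM1 by -1.92 ± 0.46. A second NUTM1 probe set differed by -0.89 ± 0.63, with overlapping groups. Without mock replicate 2, these probe sets of PLXNA1, ANK2 and ESD passed with an adjusted p of 0.0077 each, while ABHD10, ADAM33, CCNP, PRX, PADI2 and NUTM1 did not.

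**Figure D2:**
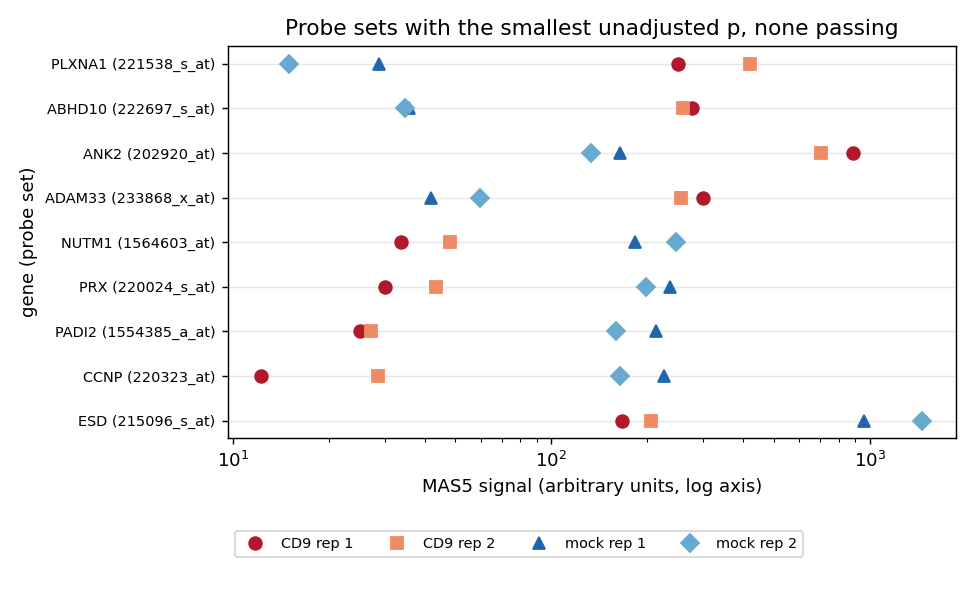
MAS5 signal (horizontal log axis, arbitrary units) in each of the 4 arrays for the 9 probe sets that the rule for named genes gave beside CD9. They are ranked within each direction, and every point is 1 array. The rule required both arrays titled CD9 to lie on one side of both arrays titled mock. An example is ESD at 167 and 206 against 962 and 1466, and none of the 9 passed the test.

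Genes were then grouped in 27 lists fixed before the data were examined, 21 of pathways and 6 of markers of other cell types. CD9 was the only member of any list past the threshold, both over all probe sets and adjusted over the list alone. In camera with a preset correlation, 1 list passed, NF-kB targets, with lower values in the arrays titled CD9. No list passed with an estimated correlation (smallest adjusted p = 0.75) or in fry (smallest adjusted p = 0.80). The estimate was 0.49 for oxidative phosphorylation, 0.36 for MHC class II, 0.30 for MHC class I and 0.25 for plasma cell genes. For others, such as tetraspanin partner proteins, it was near the preset (0.01). List calls with 1 array left out, above and below, used the preset correlation. They do not allow for members that move together this much.

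Of the 28 NF-kB targets tested, 21 had a negative and 7 a positive difference, with a median of -0.25 (camera adjusted p = 0.030, and adjusted p = 0.75 with an estimated correlation). No single member passed, so the call is on the list alone. The members with the smallest p were the chemokine CCL5 and the homing receptor CCR7. CCL5 gave 41.3 and 46.2 against 94.4 and 146 (log2 difference -1.10 ± 0.50, SE). In the arrays titled CD9 these signals lay under the array medians of 85.6 and 69.2, and without detection calls they may be background. CCR7 gave 739 and 474 against 1107 and 1369 (-1.03 ± 0.50). The NF-kB inhibitor NFKBIA differed by -0.68 ± 0.51 and lymphotoxin beta (LTB) by -0.66 ± 0.50, each by -0.32 without mock replicate 2. With that array left out CCL5 and CCR7 differed by -0.83 and -0.88, and the list kept its median of -0.25 and passed (camera adjusted p = 0.034). The list's deviation from the 4-array mean was lowest in CD9 replicate 2 (-0.23) and highest in mock replicate 2 (0.32), while CD9 replicate 1 and mock replicate 1 both stood at 0.01. Without CD9 replicate 2 the median was -0.12 and the call was lost (camera adjusted p = 0.34), as it was without mock replicate 1 (-0.49, adjusted p = 0.28) and without the intensity filter (adjusted p = 0.15). Over all alternatives its adjusted p ran from 0.013 to 0.75. Cytokines, chemokines and their receptors share CCL5, CCR7 and LTB with this list. They had a median of -0.28 over 32 genes (adjusted p = 0.056), with 21 negative, among them the tumour necrosis factor receptor TNFRSF1B at -1.11 ± 0.59. The list passed under several alternatives, quantile normalization among them, with a lowest adjusted p of 0.013. Its median was -0.05 (adjusted p = 0.24) without mock replicate 2, and TNFRSF1B differed by -0.49.

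Of the other 19 tetraspanins tested none passed, and without CD9 the list's median was -0.09 and its mean -0.01 (camera adjusted p = 0.87, a list chosen after seeing the data). With CD9 the median was -0.08 and the mean 0.42, and the camera direction was higher (adjusted p = 0.40). Without mock replicate 2 the median with CD9 was 0.24 and passed (adjusted p = 8.7e-05), but without CD9 it was 0.21 and did not (adjusted p = 0.19). UPK1B differed by 0.98 ± 0.51 (SE), TSPAN33 by 0.85 ± 0.49 and TSPAN15 by -0.63 ± 0.47, or 0.59, 1.01 and -0.28 without that array. Among 24 tetraspanin partner proteins the median was -0.06 and the mean 0.06, with camera negative and fry positive in sign (camera adjusted p = 0.93). The integrin beta 1 chain ITGB1 differed by 1.19 ± 0.59, from 3545 and 3827 in the arrays titled CD9 to 2642 and 967 in those titled mock, and by 0.48 without mock replicate 2. The growth factor HBEGF differed by -1.01 ± 0.57 and the membrane-cytoskeleton linker RDX by 0.86 ± 0.55, or -0.62 and 0.40 without mock replicate 2. Adhesion and migration genes had a median of -0.10 over 37 genes (adjusted p = 0.25), and of 0.26 without mock replicate 2 (adjusted p = 0.44). The selectin ligand SELPLG had the smallest p among them, at 38.6 and 44.4 against 149 and 114 (-1.27 ± 0.48, limma adjusted p = 1.00), and S1PR4 differed by -0.80 ± 0.50. Leaving out mock replicate 2 gave -1.44 and -0.34. The SELPLG signals in the arrays titled CD9 lay under those arrays' median signals of 85.6 and 69.2.

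Genes of the B cell state showed no list past the threshold. B cell receptor signalling genes had a median of -0.02 and a mean of 0.10 over 28 genes, with 14 in each direction (camera adjusted p = 0.68). The median was 0.07 after quantile normalization, and 0.29 without mock replicate 2, where the list passed (adjusted p = 0.0074). The scaffold BANK1 differed by 1.53 ± 0.69 (SE), MALT1 by 1.03 ± 0.75 (937 and 848 against 905 and 195), and MS4A1, which encodes CD20, by 0.53 ± 0.48 from signals of 13764 and 11332 against 13213 and 5666. These differences were 0.67, -0.02 and -0.08 without mock replicate 2. B lineage transcription factors had a median of 0.13 over 19 genes (adjusted p = 0.40), with TCF4 at 0.76 ± 0.62 and TCF3 at -0.59 ± 0.49, or -0.00 and -0.14 without mock replicate 2. Germinal centre and Burkitt lymphoma genes had a median of -0.00 and a mean of 0.18 over 22 genes (adjusted p = 0.40), and a median of 0.15 both after quantile normalization and without mock replicate 2. MYBL1 differed by 1.34 ± 1.21 (3134 and 2489 against 4368 and 261) and RGS13 by 0.91 ± 0.74 (13496 and 8490 against 12232 and 2640), but by -0.64 and -0.19 without mock replicate 2. Plasma cell genes had a median of -0.19 over 18 genes (adjusted p = 0.60), against 0.38 without mock replicate 2, which passed (adjusted p = 0.0060), with the joining chain JCHAIN at 0.45 ± 0.33 and CD27 at -0.67 ± 0.80, or 0.36 and 0.49 without that array. MHC class II genes had 17 of 21 negative differences (median -0.25, adjusted p = 0.11), HLA-DQB1 at -0.85 ± 0.52 (-0.38 without mock replicate 2). MHC class I genes had 17 of 18 negative (median -0.28, adjusted p = 0.092), ERAP1 at -0.44 ± 0.49 (-0.23 without it). The probe sets of HLA-B, HLA-C, HLA-E, HLA-F and HLA-G are all _x_at, whose probes can match other sequences. Their signs need not be independent. In both MHC lists mock replicate 2 had the highest array median, 0.54 and 0.69 above the 4-array mean, and mock replicate 1 the lowest, at -0.21 and -0.45. Without mock replicate 2 both medians were positive, 0.12 and 0.29, and neither list passed. Without mock replicate 1 both passed, with medians of -0.73 (adjusted p = 0.011) and -0.84 (adjusted p = 0.0054), and both also passed with the intensity filter at the 75th percentile.

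Mock replicate 2 also stood apart in lists of growth and metabolism. G2/M and mitosis genes had a median of 0.22 over 40 genes (camera adjusted p = 0.30). The mitotic kinase CDK1 gave 4450 and 3828 in the arrays titled CD9, 6327 in mock replicate 1 and 359 in mock replicate 2 (1.42 ± 1.23, SE), and TTK differed by 1.17 ± 1.07. Both had the opposite sign without mock replicate 2, at -0.61 and -0.51. Of the 40 genes, 17 were higher in mock replicate 2 than in mock replicate 1, so the list did not go one way. Without mock replicate 2 the G2/M median was -0.15, past the threshold in the other direction (adjusted p = 0.035). G1/S and DNA replication genes had a median of -0.16 over 35 genes (adjusted p = 0.27), with GINS2 at -0.72 ± 0.64, but without mock replicate 2 the median was 0.12 and GINS2 differed by 0.06. Ribosome biogenesis and MYC targets had a median of -0.17 over 34 genes (adjusted p = 0.30), or 0.00 after quantile normalization, with NOP58 at 1.03 ± 0.96 (3591 and 3016 against 4616 and 548). The median was 0.03 and NOP58 differed by -0.49 when mock replicate 2 was left out. Oxidative phosphorylation genes had 27 of 35 negative differences (median -0.13, adjusted p = 0.25), with NDUFA9 at -0.64 ± 0.57 (-0.00 without mock replicate 2). The list's median was 0.07 after quantile normalization and 0.36 without mock replicate 2. Its estimated inter-gene correlation was 0.49. Glycolysis and hypoxia genes had 25 of 32 negative differences (median -0.25, adjusted p = 0.092), although BNIP3L differed by 1.14 ± 0.69. This median was 0.03 and BNIP3L differed by 0.24 without mock replicate 2, while the list passed with the filter at the 75th percentile and without mock replicate 1. Cholesterol synthesis genes had a median of -0.09 and a mean of 0.06 over 19 genes, with a negative camera direction (adjusted p = 0.93), and IDI1 at 0.92 ± 0.84, against a median of 0.10 and IDI1 at -0.35 without mock replicate 2.

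Stress and survival lists also gave no call. Unfolded protein response genes had a median of -0.12 over 29 genes (camera adjusted p = 0.25), with PSAT1, an enzyme of serine synthesis, at -0.61 ± 0.49 (SE), or a median of 0.20 and PSAT1 at -0.18 without mock replicate 2. Immediate early and heat shock genes had a median of -0.12 over 22 genes (adjusted p = 0.13), with the phosphatase DUSP5 at -1.17 ± 0.60 and HSPA6 at -0.85 ± 0.46. The list's median was -0.01 without mock replicate 2, DUSP5 differed by -0.51 and HSPA6 by -0.79. Type I interferon response genes had 17 of 25 negative differences (median -0.22, adjusted p = 0.092), with OAS1 at -0.81 ± 0.50 and OAS2 at -0.84 ± 0.55, or -0.32 and -0.27 without mock replicate 2. BCL2 family and apoptosis genes had a median of -0.09 over 29 genes (adjusted p = 0.56), with the pro-apoptotic HRK at -1.11 ± 0.51 and PMAIP1 at 1.02 ± 0.67, or -0.68 and 0.13 without mock replicate 2.

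**Figure D3:**
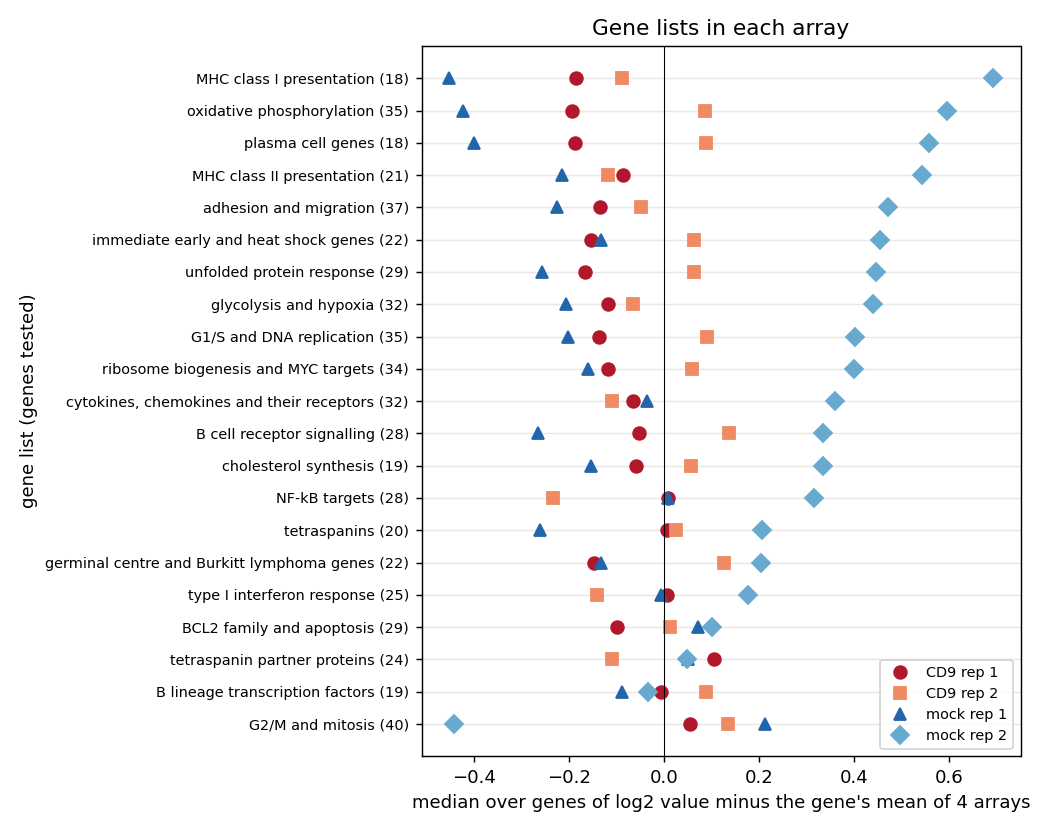
Median over the genes of each pathway list of the log2 value minus that gene's mean over the 4 arrays (horizontal axis, log2 units), for each array; the number of genes tested stands in brackets. Mock replicate 2 lies farthest from 0 in most lists, for example at 0.69 for MHC class I presentation and -0.44 for G2/M and mitosis.

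Markers of other cell types were mostly below the filter. There were 6 of 16 T cell markers above it (median difference -0.07), 4 of 12 NK cell markers (0.05, mean -0.03), 4 of 14 monocyte and macrophage markers (-0.26), 4 of 13 epithelial markers (-0.23), 7 of 14 fibroblast markers (0.14) and 5 of 9 erythroid and platelet markers (-0.54). Erythroid and platelet markers passed without the intensity filter (adjusted p = 0.027). With the filter none of these lists passed in camera, with adjusted p of 0.49, 0.76, 0.45, 0.25, 0.26 and 0.092 in the same order. The medians were 0.43, -0.03, -0.14, -0.22, 0.60 and -0.36 in that order without mock replicate 2. The 3' to 5' signal ratio of the ACTB control probe sets, a measure of RNA integrity and labelling length, was 2.20 and 1.62 in the arrays titled CD9 and 2.26 and 1.58 in those titled mock. For GAPDH it was 0.814 and 0.941 against 0.853 and 0.922. The control probe set for the 3' part of 18S ribosomal RNA gave 245 and 142 in the arrays titled CD9, 112 in mock replicate 1 and 458 in mock replicate 2. The mean log2 ratio differed between the groups by 0.0017 for ACTB and -0.0199 for GAPDH, less than the spread within either group. With 2 arrays per group, an exact permutation test cannot go below p = 0.333.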

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

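All alternatives were fixed before the data were examined except array weights. The CD9 difference stayed past the threshold under all 13 alternatives run, at 7.29 to 9.20 on the log2 scale with adjusted p from 1.6e-36 to 0.033. One probe set, CD9, was called under each alternative except 3: the count was 2 with the replicate block (CD9 and PLXNA1, 2 probe sets changed at least 2-fold) and, with 1 array left out, 1 to 5765, with 1 to 5159 probe sets changed at least 2-fold. The high end came without mock replicate 1. Without mock replicate 2 the count was 12, namely CD9, ANK2, ESD, ETV6, FAM30A, NPLOC4, PLXNA1, POLD4, SPNS1, TMEM141 and probe sets with several symbols; those not named elsewhere were named after their values were seen. Whether the replicate numbers pair the arrays is undecided, since the labels tie them to no batch and there are only 2 pairs: the differences between replicates 2 and 1 correlated between the groups at 0.25 across probe sets. With the block PLXNA1 had a limma adjusted p of 0.0087 and the list NF-kB targets a camera adjusted p of 0.065. The prior degrees of freedom were infinite in that limma fit. Its p-values therefore rest on the fitted trend and not on each probe set's own spread. The number of lists past the threshold was 1, and became 2 with quantile normalization, without a filter, without the trend or with probe sets averaged. It was 5 with the filter at the 75th percentile, 0 with the replicate block or an estimated correlation, 4 with array weights (added after seeing the data) and 0 to 8 with 1 array left out. The replicate block changed no other call. Array weights were 2.38 for each array titled CD9 and 0.42 for each titled mock. With 2 arrays per group they are equal within a group, so they cannot single out mock replicate 2. Without mock replicate 2, 5 lists that had not passed did so with a median of the opposite sign (for tetraspanins and B cell receptor signalling the camera direction was higher in both cases): with 1 array left out, the median of tetraspanins ranged from -0.24 to 0.24, of B cell receptor signalling from -0.39 to 0.29, of plasma cell genes from -0.45 to 0.38, of G2/M and mitosis from -0.15 to 0.48 and of oxidative phosphorylation from -0.67 to 0.36. The cause was not tested. A sign change with neither value past the threshold was not counted as a reversal: it occurred in 4 of 27 lists with quantile normalization, 6 without CD9 replicate 1, 2 with probe sets averaged, and 1 each without CD9 replicate 2, without a filter and with the higher filter (21 lists). Reversals included, it was 16 of 27 without mock replicate 2. Rescaling to 1 trimmed mean changed nearly nothing, since the arrays already had it, and says nothing about stability. The median difference of all tested probe sets was 0.03 as deposited and 0.01 after quantile normalization. Without detection calls, signals near the offset of 21.2 cannot be ordered.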

Other observations

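All tests in this part were chosen after the results they bear on had been seen. Outside the lists, 4 genes had at least 2 probe sets at an unadjusted p under 0.05 in the same direction, although none passed after adjustment in limma. All 5 tested probe sets of ETV6, a transcriptional repressor of the ETS family, were lower in both arrays titled CD9 than in both titled mock, with log2 differences from -2.09 to -0.56, for example signals of 196 and 170 against 797 and 469. ESD was lower at 3 of 4 probe sets without overlap, and ANK2 higher at both of its probe sets. GATM, the enzyme of the first step of creatine synthesis, was higher at both of its probe sets, at 1502 and 1257 against 544 and 412 in one and with a log2 difference of 1.46 in the other. ETV6 and GATM were named after their values were seen.

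Probe-level noise is argued against as the whole source of this agreement: in 10000 shuffles of gene names over the probe sets, the central 95% ran from 0 to 2 such genes, against 4 observed. Variation between cultures that has nothing to do with CD9 may account for it, but the splits of the 4 arrays cannot decide this. The other 2 splits gave 6 and 294 such genes, from 460 and 2788 probe sets at an unadjusted p under 0.05. The split by title gave 4 from 157, and a larger pool can give more such genes by itself. Clones or transfections that differ by title, and an effect of CD9 itself, remain untested by this design.

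Mock replicate 2 stood apart from mock replicate 1 in several gene groups. From mock replicate 1 to mock replicate 2, MHC class I genes had a median difference of 1.18 on the log2 scale, oxidative phosphorylation genes of 0.94 (31 of 35 positive) and G2/M genes, which went both ways (17 of 40 positive), of -0.70, while between the arrays titled CD9 the same medians were 0.06, 0.20 and -0.03. The first principal component held 75.6% of the variance, with scores of -43.3 and -13.6 for the arrays titled CD9, -72.5 for mock replicate 1 and 129 for mock replicate 2. Array scaling is argued against as the whole cause, since after quantile normalization the smallest SD of log2 differences to this array was 0.92, against 0.54 to 0.62 among the other arrays. RNA degradation that raises the 3' to 5' ratio in this array alone was not seen at either control transcript, but is not excluded. The ACTB log2 ratio was 0.66, the lowest of the 4 arrays (0.70 to 1.17 in the others). The GAPDH one was -0.12, within the others' range of -0.30 to -0.09 but above mock replicate 1 at -0.23. Other differences in the RNA stay open too, with an 18S ribosomal RNA signal of 458 against 112 to 245. A large share of RNA from the 6 listed cell types is argued against, since 0% of each type's markers reached the array's 90th percentile of 759. A small share stays open. CD5 was the highest of 16 T cell markers (median 47.9), at 535 against 44.7 in mock replicate 1 and 127 and 162 in the arrays titled CD9. Of the 6 T cell markers tested, 5 were higher in mock replicate 2 than in mock replicate 1, but CD2 was lower, at 47.7 against 104. Another B cell line, a different growth state, and a labelling bias by transcript length or GC content were not tested and may still apply, and no biological explanation was tested since the labels give both replicates the same treatment.

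Of the 3 splits of the arrays into pairs, the split by title gave 1 probe set past the threshold, CD9, and the others 0. CD9 is the gene on the transfected plasmid, so this count does not compare the groupings. With 3 splits no share can fall under 0.05. At an unadjusted p under 0.05 the split by replicate number called 2788 probe sets, against 157 by title, 460 by the third split and 1365 by chance, which points to a structure of the samples. The split by number sets mock replicate 2 beside the array nearest to it, CD9 replicate 2 (SD of log2 differences 0.95). Array measures also went with the number, with ACTB 3' to 5' ratios of 2.20 and 2.26 in replicates 1 and 1.62 and 1.58 in replicates 2, GAPDH ratios of 0.814 and 0.853 against 0.941 and 0.922, and median signals of 85.6 and 82.8 against 69.2 and 69.1. With 2 pairs and no batch in the labels, a batch by number is neither shown nor excluded.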
